A study of Homo sapiens with 8 samples.

How the data were processed

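RNA was sequenced from 8 libraries of 2 liver cancer cell lines, PLC and Huh7. Each line gave 1 library in each of 4 groups: control cells with vehicle, control cells with ARV-825, senescent cells with vehicle and senescent cells with ARV-825. ARV-825 is a proteolysis-targeting chimera (PROTAC) that recruits the E3 ligase receptor CRBN to BET proteins and leads to their degradation, and treatment lasted 48 h per the labels. The labels name palbo and KPT330 as the inducer of senescence in PLC and palbo alone in Huh7. Palbociclib inhibits CDK4/6 and KPT-330 (selinexor) inhibits the nuclear export protein XPO1. The state comparison therefore did not carry the same inducer in both lines. Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols.

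The deposited table held 1 FPKM value per gene and library (fragments per kilobase of gene, scaled to library size), and no other unit was used. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, STAR 2.4.2g1, featureCounts and Subread with the genome build GRCh38. Whether strand was used in counting, how reads with several matches were treated and what made the FPKM values were not given in the sources used here. Reads of a gene and of an antisense or overlapping partner are therefore uncertain. Of 50870 lines, 50867 were used as genes. The entry of TGFB1 was broken over 3 lines and was left out. A spreadsheet had turned 28 symbols into dates, and these were resolved through the gene identifiers. Current symbols were found for 49658 identifiers, 98.5% of identifiers were in GENCODE release 29, and 94.8% had the same coordinates there. Coordinates are those of the deposited table, on GRCh38.

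Depth was read from the low values, which step by the worth of 1 fragment. Among genes with 1 annotated transcript longer than 1500 bases, 96.92% to 97.92% of the low values per library were whole fragment numbers within 0.05 fragments. The steps gave 6015000 to 6613000 fragments per library, so that 1 FPKM in a gene of 2 kb stood for 12.0 to 13.2 fragments. These estimates describe depth and were not used for testing, because fragment numbers recovered from FPKM depend on each gene's length. Depth was therefore close between libraries, and genes near 1 FPKM rested on few fragments.

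Several genes carried values that the upstream assignment of reads may have decided. MT-ATP6, MT-ATP8, MT-CO3, MT-ND3, MT-ND4 and MT-ND4L were listed at 0 in all 8 libraries. MT-ND1 was at 1080 FPKM in the PLC control vehicle library and 26.2 in the PLC control ARV-825 library, while MT-ND2 was at 14.1 and 1572, so single mitochondrial genes were not interpreted. Some processed pseudogenes stood far above their parents: EEF1A1P5 was at 4780 FPKM and EEF1A1 at 206 in the PLC control vehicle library. They may hold reads of their parents, which was not tested. Ribosomal protein genes, housekeeping genes and histone genes, which have near-identical copies, are uncertain for the same reason.

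The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with cell line and group as terms, empirical Bayes moderation with a trend on mean expression, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. All 8 libraries entered 1 fit with 3 residual and 4.15 prior degrees of freedom. Genes with at least 1 FPKM in at least 2 libraries were tested, which left 15863. A fold change on this scale understates the change of low genes. The cell line pairs the libraries across groups and was a block in the fit: the lowest correlation of log2 values between libraries within a line was 0.837 and the highest between lines was 0.803. Nothing in the labels says that libraries came from separate cultures beyond the 2 lines. The p-values therefore measure only the spread between these 2 lines.

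The contrasts were fixed before the data were examined, together with the test, the filter, 42 gene lists, the rule for named genes and most alternatives. They were senescent against control with vehicle, ARV-825 against vehicle in control cells, the same in senescent cells, and the difference of these responses. A contrast of ARV-825 against vehicle averaged over both states was chosen after seeing the data, as were the list of replication-dependent histone genes and the list of RNA genes without a poly(A) tail. Genes named are 14 fixed genes; the 10 highest and 10 lowest per contrast by the smaller of the 2 lines' absolute log2 changes among genes that passed and moved the same way in both lines, filled from genes that did not pass where fewer than 10 did; and the 2 to 4 members of each described list with the largest absolute mean change. Beside the test, genes with at least a 2-fold change in the same direction in both lines were counted, with those in opposite directions as the level that noise and line differences give. The opposite count pools 2 patterns, higher in PLC with lower in Huh7 and the reverse, so it is to be set against the higher and lower counts together.

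Gene lists were tested with camera on the same fit, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 42 lists. The lists held 902 genes, of which 786 were measured, and every list had at least 3. In each line, the median change of a list was placed among 10000 random lists of the same size matched on expression. The fit was tested on simulated data with 200 changed genes among the 15863 for ARV-825 against vehicle in control cells. It recovered 4% of genes changed 2-fold, 48% at 4-fold, 72% at 8-fold and 88% at 16-fold, with 0 false calls. In this setting, changes under 4-fold would mostly be missed. The simulated noise was independent between genes and few genes were changed, so these rates need not hold for the real data. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

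Alternatives covered pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, other scalings (each library rescaled to TPM, TMM factors and quantile normalization), no cell line block, the 4 libraries of a contrast alone, no trend, protein-coding genes alone, a block for each line and state (for the averaged contrast) and each library left out in turn. A leave-one-out fit leaves a group with 1 library, which is then assumed to vary like the other groups. The fit fills in the missing library from the difference between the lines in the other groups. A list can therefore change direction in such a fit though neither line did. Rescaling to TPM took the median log2 change of all genes with ARV-825 in senescent Huh7 cells from −0.109 to −0.226, the largest such shift, as values summed to between 204799 and 229683 per library. It also lowered the weight of the pseudocount.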

Results

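The data were FPKM values for 50867 genes in 8 libraries, 1 per combination of cell line (PLC or Huh7, both liver cancer lines), state (control or senescent) and treatment (vehicle or the BET-degrading PROTAC ARV-825 for 48 h). Each of the 4 groups thus held 2 libraries, 1 per line, and every value with an error below has n = 2 lines. Estimated depth was 6015000 to 6613000 fragments per library, and 22151 to 25381 genes had a value above 0. The cell line was the main axis of the data. The first principal component held 57.1% of the variance and parted PLC from Huh7. The second held 18.4% and parted ARV-825 from vehicle, and the third held 8.6% and followed the state. Changes are log2 differences of FPKM + 1, with the standard error from the limma fit.

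Libraries with ARV-825 had more of their total in few genes. The 10 highest genes held 18.37% and 19.63% of the total in the control and senescent PLC libraries with ARV-825, against 12.23% and 15.61% with vehicle. In Huh7 they held 18.44% and 16.02% with ARV-825 and 13.84% and 12.39% with vehicle. Mitochondrial genes held 6.32% to 13.18%, with the highest share in senescent PLC cells with ARV-825.

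The first comparison asked how senescent cells differed from control cells with vehicle. Genes were ranked by the smaller of the changes in the lines. ANKRD1, a target of the YAP transcription coactivator, went from 6.72 to 47.8 FPKM in PLC and from 3.44 to 110 in Huh7, a log2 difference of 3.65 ± 0.52. The peptide EDN1 (endothelin 1) was higher by 3.11 ± 0.50, the membrane repair protein MYOF by 2.4 ± 0.30, the lipase LIPH by 2.67 ± 0.33 and the peptidase DPP4, a surface marker reported on senescent cells, by 2.29 ± 0.37. The plasma protein gene AHSG went from 99.0 to 8.49 FPKM in PLC and from 289 to 46.5 in Huh7, and the stress-induced mTORC1 inhibitor DDIT4 from 377 to 59.3 and from 28.2 to 4.64, a difference of −2.51 ± 0.44. The apolipoprotein APOC3 had a difference of −2.62 ± 0.55, the transferrin gene TF −1.90 ± 0.47, the prothrombin gene F2 −1.70 ± 0.49 and the cystine transporter SLC7A11 −2.08 ± 0.37.

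None of these genes passed the test. limma called 0 of 15863 genes, with 788 at an unadjusted p under 0.05 where chance gives 793, and the lowest adjusted p was 0.532. At least a 2-fold difference in the same direction in both lines was seen for 69 genes higher and 55 lower. Opposite directions, in either order of the lines, were seen for 64 genes. Across genes, the changes in PLC and Huh7 had a Pearson correlation of 0.095 and a Spearman correlation of 0.074. Genes are not independent replicates, and the inducer differed between the lines. The cell cycle inhibitor CDKN1A (p21) differed by 0.21 ± 0.38, the lamin LMNB1, reported to be lost in senescence, by −0.10 ± 0.60 and the proliferation marker MKI67 by 0.22 ± 0.49. Both MKI67 and LMNB1 were higher in senescent PLC cells and lower in senescent Huh7 cells. CRBN, the receptor that ARV-825 recruits, differed by −0.02 ± 0.23. XPO1 differed by 0.20 ± 0.27, with 0.51 in PLC, where the labels name its inhibitor, and −0.12 in Huh7. BRD4, a BET protein, was at −1.24 in PLC and −0.11 in Huh7. Its level in the PLC control vehicle library was above that in every other PLC library.

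As groups, 14 of the 42 lists shifted in senescent cells by camera with the preset correlation, and 0 with an estimated one. Integrated stress response genes, which cells switch on when translation is restrained, fell with a median log2 change of −1.29 in PLC and −0.58 in Huh7 (camera adjusted p = 4.96e-11; adjusted p = 0.701 with an estimated correlation). Of 23 measured members, 13 were lower in both lines and 0 higher, with 0 passing over all genes and 8 lower adjusted over the list alone. The kinase-like regulator TRIB3 was at −2.10 ± 0.49 and the hormone STC2 at −2.16 ± 0.41. Hepatocyte secreted proteins fell (camera adjusted p = 1.2e-07; adjusted p = 0.702 with an estimated correlation). In both lines 21 of 36 were lower and 4 higher, with 0 passing over all genes and 2 adjusted over the list alone, and TTR (transthyretin) went the other way at 1.98 ± 0.78. Cholesterol synthesis and uptake genes fell (camera adjusted p = 3.88e-05; adjusted p = 0.733 with an estimated correlation), with 18 of 24 lower in both lines and INSIG1, a sterol sensor, at −1.44 ± 0.64. Liver transcription factors were called lower (camera adjusted p = 0.00134, and 0.701 with an estimated correlation), with medians of −0.37 in PLC and −0.23 in Huh7. In Huh7 the median stood at percentile 7.52 of random lists, within their middle range. The call was lost without PLC control vehicle and without PLC senescent vehicle. FOXA3 was at −1.24 ± 0.42 and the bile acid receptor NR1H4 at −0.93 ± 0.35. Hepatic metabolism enzymes (camera adjusted p = 0.0149; adjusted p = 0.701 with an estimated correlation) and fatty acid genes (camera adjusted p = 0.0048; adjusted p = 0.702 with an estimated correlation) fell too. The urea cycle enzyme CPS1 was at −1.28 ± 0.42 and the desaturase SCD at −1.21 ± 0.66. Epithelial-mesenchymal and matrix genes were called higher (camera adjusted p = 8.53e-06; adjusted p = 0.733 with an estimated correlation), with medians of 0.07 in PLC, where the mean was −0.03, and 1.34 in Huh7 and the matrix protein SPARC at 2.02 ± 0.72. Secretory factors of senescence were called higher (camera adjusted p = 0.0022; adjusted p = 0.798 with an estimated correlation), with medians of 0.00 in PLC, where the mean was −0.32, and 1.02 in Huh7. 4 of 29 were higher adjusted over the list alone and 0 over all genes, with CXCL1 at 1.94 ± 0.43 and SERPINE1 the other way at −2.10 ± 0.99. Lysosome genes were called higher (camera adjusted p = 0.000121, and 0.798 with an estimated correlation), with medians of 0.04 in PLC and 0.66 in Huh7. In PLC the median stood at percentile 19.71 of random lists, so no rise relative to other genes was seen there. Of 31 members 18 were higher in both lines, with GBA1, mutated in Gaucher disease, at 0.92 ± 0.25. The heat shock list was called higher (camera adjusted p = 0.00134, and 0.701 with an estimated correlation), with medians of 0.58 in PLC and 0.09 in Huh7. In Huh7 the median stood at percentile 84.77 of random lists, within their middle range. The call was lost without PLC control vehicle. The collagen chaperone SERPINH1 was at 1.13 ± 0.33. Cell cycle and E2F targets were called higher (camera adjusted p = 5.37e-05; adjusted p = 0.941 with an estimated correlation), but the medians were 1.01 in PLC and −0.27 in Huh7, and 47 of 59 members had opposite signs in the lines. Immediate early genes were called lower (camera adjusted p = 0.00674; adjusted p = 0.798 with an estimated correlation) with medians of −1.23 in PLC and 0.06 in Huh7. Ribosomal protein genes were called lower (camera adjusted p = 0.000461, and 0.823 with an estimated correlation). Mitochondrially encoded genes were called higher (camera adjusted p = 0.0127, and 0.701 with an estimated correlation). Both lists may hold reads that near-identical copies share, which was not tested. The ribosomal medians were 0.19 in PLC and −0.66 in Huh7. In all lists of this paragraph apart from the 3 given counts, 0 members passed over all genes and 0 adjusted over the list alone. Of the 14 calls, 5 were lost or turned without the PLC control vehicle library, 7 without the Huh7 control vehicle library, 6 without the PLC senescent vehicle library and 3 without the Huh7 senescent vehicle library. Without the PLC control vehicle library the cell cycle list was called lower (camera adjusted p = 0.000318) and the immediate early list higher (camera adjusted p = 0.0314), and the lysosome call was lost without the Huh7 control vehicle library (camera adjusted p = 0.816). Without that library the secretory factors turned, with a mean change of −0.23 relative to all genes (camera adjusted p = 0.41), as did the ribosomal genes at 0.04 (camera adjusted p = 0.701). Hepatocyte secreted proteins and the integrated stress response were called with every library left out, the latter with a camera adjusted p of 0.0376 without PLC control vehicle.

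ARV-825 in control cells asked what degradation of BET proteins does to liver cancer cells without senescence. Of the 14 genes that passed, 4 of the 5 that rose were histone genes, and 9 fell. The histone gene H2BC5 (ENSG00000158373, chromosome 6, 26158146 to 26171349 on GRCh38) rose by 4.37 ± 0.38 on the log2 scale (limma adjusted p = 0.0332), at 4.52 in PLC and 4.23 in Huh7. H3C10 (chromosome 6, 27810064 to 27811300) rose by 4.20 ± 0.38, H2AC11 (chromosome 6, 27133042 to 27135291) by 4.05 ± 0.42 and H4C12 (chromosome 6, 27831216 to 27831527) by 3.36 ± 0.32. TM4SF4, a tetraspanin-like membrane protein of liver and intestine (ENSG00000169903, chromosome 3, 149473974 to 149503281), went from 50.2 to 1.45 FPKM in PLC and from 12.8 to 0.248 in Huh7, a change of −3.92 ± 0.31 (limma adjusted p = 0.0332).

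The other genes that fell were SLC51B, the beta subunit of a bile acid exporter (chromosome 15, 65045370 to 65053396), at −3.61 ± 0.40, and S100A16, a calcium-binding protein (chromosome 1, 153606886 to 153613145), at −3.35 ± 0.30. The acetyltransferase NAT8 (chromosome 2, 73640832 to 73642393) was at −2.79 ± 0.27. OAF (chromosome 11, 120210767 to 120230332) fell by 2.65 ± 0.29, the cationic amino acid transporter SLC7A1 (chromosome 13, 29509410 to 29595688) by 2.19 ± 0.22, and ZHX2, a repressor of fetal liver genes (chromosome 8, 122781394 to 122974512), by 2.08 ± 0.22. MPZL3 (chromosome 11, 118226690 to 118252350) fell by 1.88 ± 0.21, and ENSG00000167774, named here by its identifier, by 3.02 ± 0.29. A further entry, ENSG00000279602, rose by 2.25 ± 0.25. In all, limma called 14 genes, 5 higher and 9 lower, with adjusted p from 0.0332 to 0.0425, and 2622 genes had an unadjusted p under 0.05. At least a 2-fold change in both lines was seen for 177 genes higher and 333 lower, with 39 in opposite directions. More histone genes filled the 10 highest without passing, among them HIST1H3B at 5.67 ± 0.99 (limma adjusted p = 0.0779), and TM4SF1 was at −3.06 ± 0.49 (limma adjusted p = 0.0709). The number called depended on single libraries: 0 were called without PLC control vehicle, PLC control ARV-825, PLC senescent vehicle, PLC senescent ARV-825, Huh7 control ARV-825 or Huh7 senescent vehicle, 1 without Huh7 senescent ARV-825, and 16 without Huh7 control vehicle, of which 4 were shared. Without a filter, without the line block or with a pseudocount of 5, 0 were called.

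Among the fixed genes, SERPINI1, a gene reported to rise with BET inhibitors, was higher by 1.35 ± 0.23 (limma adjusted p = 0.0774). HEXIM1, an inhibitor of transcription elongation that BET inhibitors are reported to raise, was higher by 0.74 ± 0.39 (limma adjusted p = 0.392). BRD2 was higher by 0.74 ± 0.27, BRD3 by 0.35 ± 0.23, and BRD4 was at −1.25 in PLC and 0.28 in Huh7. In PLC, BRD4 was at 22.8 FPKM with control vehicle and 9.03 with control ARV-825. In senescent PLC cells it was at 9.13 with vehicle and 9.64 with ARV-825. The PLC fall here and that in senescent against control cells therefore share the control vehicle library and are not independent. The oncogene MYC, which BET inhibition lowers in many blood cancers, was at −1.5 in PLC and 0.51 in Huh7. CRBN differed by 0.24 ± 0.23, and its ligase partners DDB1 by −0.11 ± 0.30 and CUL4A by −0.55 ± 0.24. None of these passed.

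**Figure D1:**
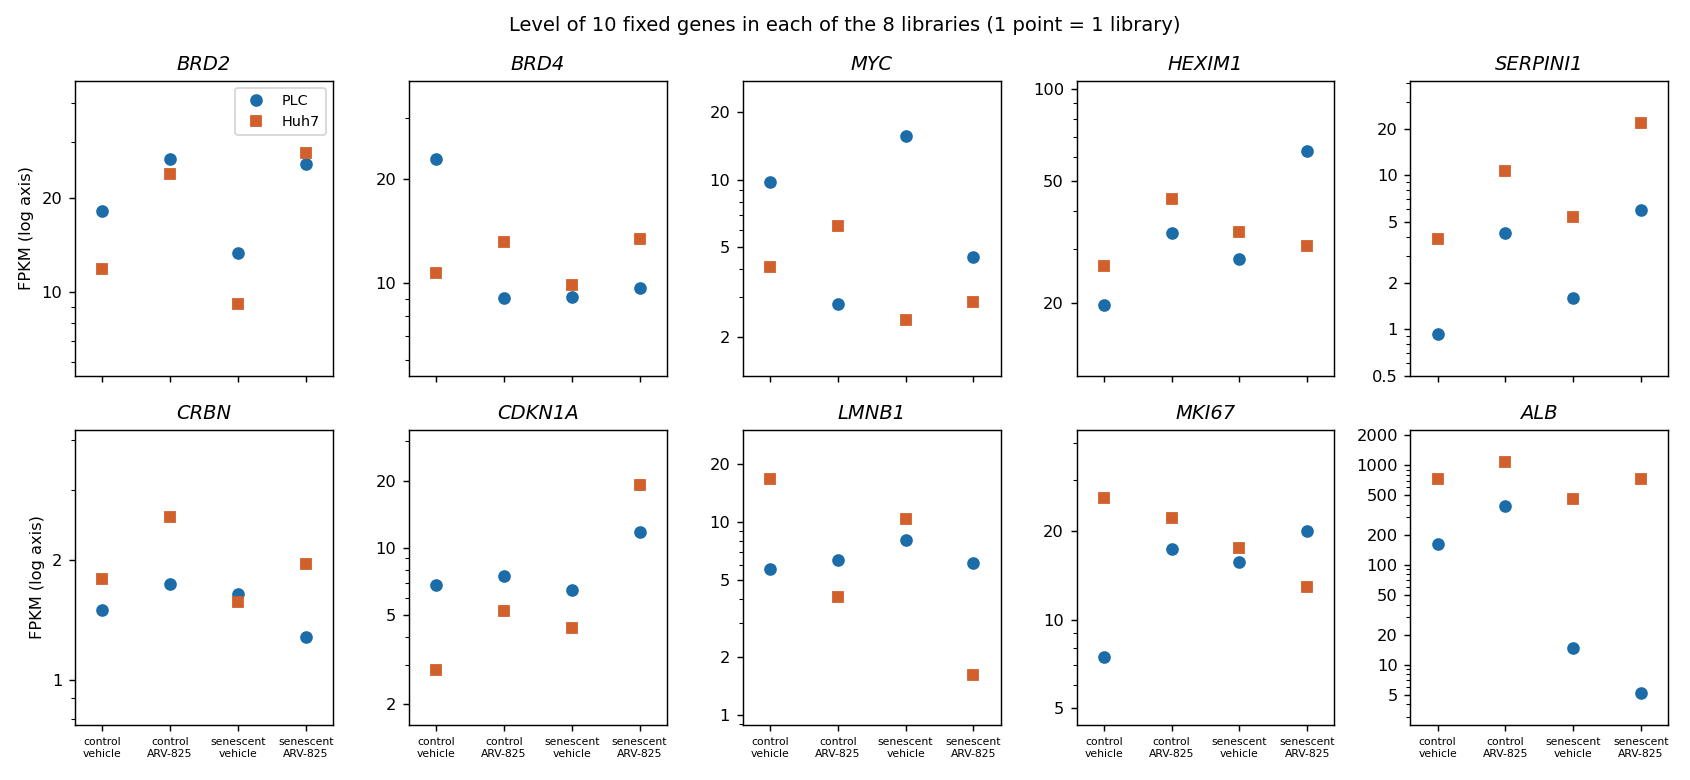
FPKM (log axis) of 10 of the genes fixed before the data were examined in each of the 8 libraries, with circles for PLC and squares for Huh7. SERPINI1 was higher with ARV-825 in both lines and states, whereas MYC was lower with ARV-825 in PLC and higher in Huh7.

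As groups, 9 lists shifted with ARV-825 in control cells with the preset correlation, and 0 with an estimated one. BET inhibitor response markers reported to rise did so in both lines for 9 of 9 members (camera adjusted p = 7.36e-09; adjusted p = 0.366 with an estimated correlation), with 1 passing over all genes and 6 adjusted over the list alone. After H2BC5, their largest members were the histone genes H2BC21 at 3.23 ± 0.79, H2AC6 at 3.06 ± 0.38 and H2BC4 at 3.02 ± 0.44. These genes, H2BC5 included, are also in the histone list chosen after seeing the data. The 2 results overlap in each ARV-825 comparison, and the limits given further on for the histone rise hold here too. Integrated stress response genes fell (camera adjusted p = 4.95e-07; adjusted p = 0.678 with an estimated correlation), 16 of 23 lower in both lines and 0 higher, with 0 passing over all genes and 10 adjusted over the list alone. TRIB3 was at −3.23 ± 0.49, STC2 at −2.64 ± 0.41 and the serine synthesis enzyme PHGDH at −1.94 ± 0.29. NF-kB targets fell (camera adjusted p = 3.95e-05; adjusted p = 0.678 with an estimated correlation), 16 of 19 lower in both lines, with 0 passing over all genes and 7 adjusted over the list alone. The chemokines CCL20 and CXCL8 were at −2.91 ± 0.58 and −2.29 ± 0.98. Secretory factors of senescence, which share these chemokines, fell as well (camera adjusted p = 0.00118; adjusted p = 0.828 with an estimated correlation), with 3 of 29 lower adjusted over the list alone and 0 over all genes. Interferon-stimulated genes fell (camera adjusted p = 0.00249; adjusted p = 0.828 with an estimated correlation), 13 of 21 lower in both lines and 5 adjusted over the list alone, with 0 over all genes. OAS3, an RNA sensor of viral infection, was at −1.5 ± 0.34. Antigen presentation genes fell (camera adjusted p = 0.00954; adjusted p = 0.678 with an estimated correlation), 10 of 12 lower in both lines, with the peptide transporter TAP1 at −1.05 ± 0.27. Hepatic metabolism enzymes fell (camera adjusted p = 0.0121; adjusted p = 0.678 with an estimated correlation), 13 of 20 lower in both lines, with 2 adjusted over the list alone, 0 over all genes and the urea cycle enzyme ASS1 at −1.49 ± 0.36. NRF2 targets rose (camera adjusted p = 0.00986; adjusted p = 0.678 with an estimated correlation), with medians of 1.04 in PLC and 0.06 in Huh7, 4 higher and 1 lower adjusted over the list alone and 0 over all genes. The ferritin light chain FTL was at 2.21 ± 0.47. Lysosome genes rose (camera adjusted p = 0.00222; adjusted p = 0.833 with an estimated correlation), 20 of 31 higher in both lines, with the sialidase NEU1 at 1.82 ± 0.38 and the calcium channel MCOLN1 at 1.15 ± 0.38. In the lysosome and antigen presentation lists 0 members passed over all genes and 0 adjusted over the list alone. Of the 9 calls, 4 were lost without the PLC control vehicle library, 2 without Huh7 control vehicle, 2 without PLC control ARV-825 and 1 without Huh7 control ARV-825. The response markers, NF-kB targets and the integrated stress response were called with every library left out, the last with a camera adjusted p of 0.0335 without PLC control vehicle.

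In senescent cells, ARV-825 addressed the vulnerability named in the title of the series, and the genes ranked highest by the smaller of the changes in the lines were histone genes, with TM4SF4, NAT8, S100A16 and OAF among the lowest. H3C10 was higher by 3.87 ± 0.38 and H2BC5 by 4.02 ± 0.38 (limma adjusted p = 0.0688 for both). TM4SF4 was at −2.95 ± 0.31, NAT8 at −2.97 ± 0.27, S100A16 at −2.72 ± 0.30 and OAF at −2.57 ± 0.29, all with the same limma adjusted p of 0.0688. FABP1, the liver fatty acid binding protein, was at −2.52 ± 0.38 (limma adjusted p = 0.129), and the transcription factor ETV4 at −2.55 ± 0.44 (limma adjusted p = 0.146). SERPINI1 was higher by 1.63 ± 0.23, BRD2 by 1.19 ± 0.27 and CDKN1A by 1.34 ± 0.38, with 0.78 in PLC and 1.90 in Huh7 for the last.

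None passed: limma called 0 genes, with 2263 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0688. At least a 2-fold change in both lines was seen for 146 genes higher and 233 lower, with 39 in opposite directions. LMNB1 was at −0.34 in PLC and −2.13 in Huh7, and MYC at −1.58 and 0.19. CRBN differed by −0.01 ± 0.23 and XPO1 by −0.01 ± 0.27. The threshold was close under some other settings: 9 genes were called with a filter at 5 FPKM, 9 among protein-coding genes alone and 14 from the 4 libraries of senescent cells alone. Leaving out a library did not bring any gene past it.

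As groups, 10 lists shifted with ARV-825 in senescent cells with the preset correlation, and 0 with an estimated one. BET inhibitor response markers rose (camera adjusted p = 7.65e-12; adjusted p = 0.243 with an estimated correlation), 8 of 9 higher in both lines, with 7 adjusted over the list alone and 0 over all genes. H2BC4 was at 2.95 ± 0.44. Lysosome genes rose (camera adjusted p = 5.24e-07; adjusted p = 0.798 with an estimated correlation), 20 of 31 higher in both lines, with 1 adjusted over the list alone and 0 over all genes. NEU1 was at 2.14 ± 0.38 and MCOLN1 at 1.55 ± 0.38. NRF2 targets rose (camera adjusted p = 0.000356; adjusted p = 0.782 with an estimated correlation), with 3 adjusted over the list alone and 0 over all genes. The antioxidant enzymes SRXN1 and TXNRD1 were at 2.66 ± 0.46 and 1.81 ± 0.34. Autophagy genes were called higher (camera adjusted p = 0.0443; adjusted p = 0.798 with an estimated correlation), with medians of −0.06 in PLC and 0.39 in Huh7, 1 of 23 higher adjusted over the list alone and 0 over all genes. The cargo receptor SQSTM1 was at 2.10 ± 0.32. Targets of p53 rose (camera adjusted p = 0.0119; adjusted p = 0.671 with an estimated correlation), 14 of 23 higher in both lines, with CDKN1A among them. Immediate early genes rose (camera adjusted p = 0.0251; adjusted p = 0.798 with an estimated correlation), with EGR1 at 2.01 ± 1.04 and 0 passing over all genes. The 1 member past the threshold adjusted over the list alone, the phosphatase DUSP6, was lower at −1.58 ± 0.33. The CRBN E3 ligase and its regulators fell (camera adjusted p = 0.0276; adjusted p = 0.798 with an estimated correlation), 15 of 22 lower in both lines, with the NEDD8-conjugating enzyme UBE2M at −0.87 ± 0.25 and the ligase subunit RBX1 at −0.79 ± 0.41. Proteasome genes were called lower (camera adjusted p = 0.0162; adjusted p = 0.854 with an estimated correlation), with medians of −0.03 in PLC and −0.72 in Huh7 and the catalytic subunit PSMB6 at −1.38 ± 0.34. Hepatic metabolism enzymes fell (camera adjusted p = 0.0124, and 0.671 with an estimated correlation). Nuclear genes of oxidative phosphorylation were called lower (camera adjusted p = 0.0334, and 0.798 with an estimated correlation). Their medians were −0.33 in PLC and −0.29 in Huh7, where −0.29 stood at percentile 24.07 of random lists, within their middle range. HPD, of tyrosine breakdown, was at −1.23 ± 0.37 and NDUFS2, of complex I, at −1.01 ± 0.27. In the p53, E3 ligase, proteasome, hepatic metabolism and oxidative phosphorylation lists 0 members passed over all genes and 0 adjusted over the list alone. Of the 10 calls, 7 were lost or turned without the Huh7 senescent ARV-825 library, 6 without PLC senescent vehicle and 3 without Huh7 senescent vehicle. Without the Huh7 senescent ARV-825 library the proteasome list turned, with a mean change of 0.066 relative to all genes. Only the response markers were called with every library left out. The calls of all other lists in this paragraph, the CRBN E3 ligase and its regulators among them, depended on single libraries.

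**Figure D2:**
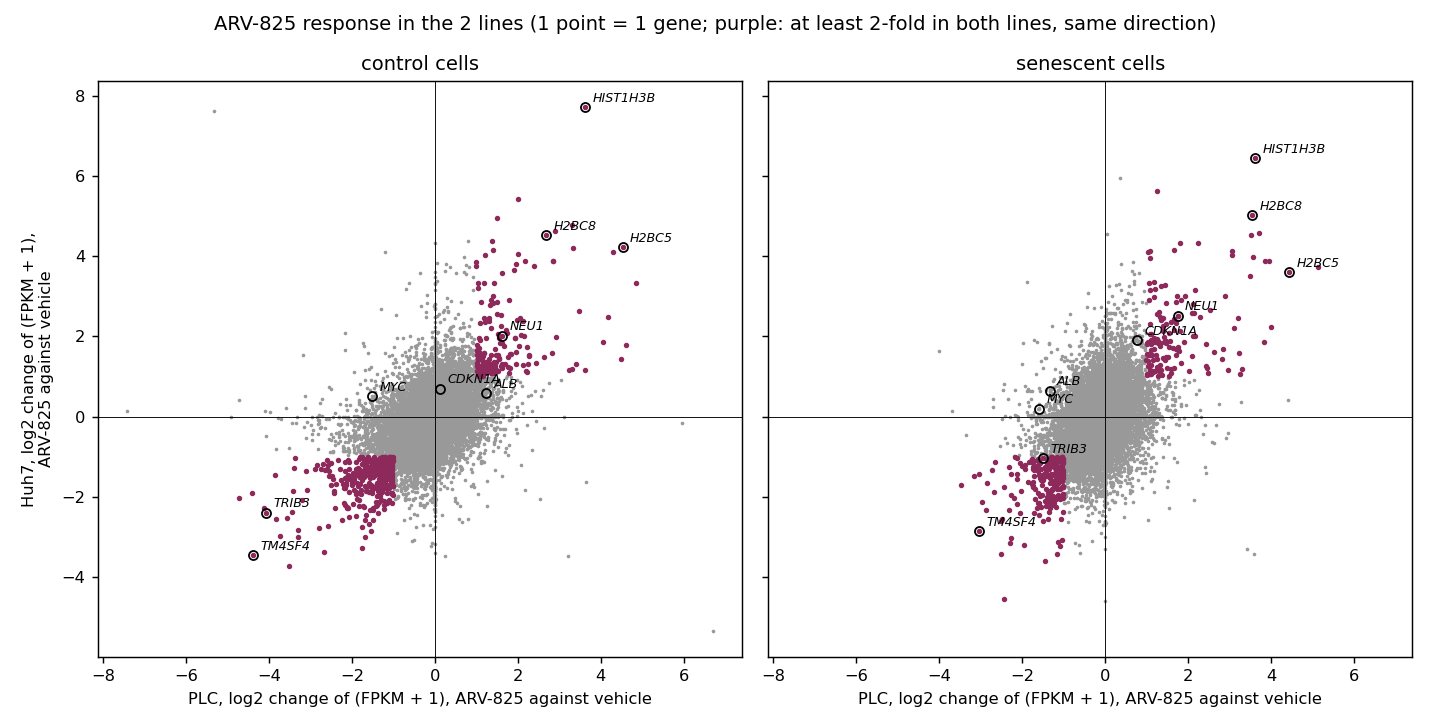
Log2 change of FPKM + 1 with ARV-825 against vehicle in PLC (horizontal) and Huh7 (vertical), 1 point per gene, for control cells (left) and senescent cells (right), with genes changed at least 2-fold the same way in both lines in purple. Across 15863 genes the Pearson correlation between the lines was 0.406 in control cells and 0.380 in senescent cells.

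The response to ARV-825 was then compared between the states. Among the genes with the highest values in both lines, the chemokine CCL20 had a difference of 3.23 ± 0.83, with 2.95 in PLC and 3.51 in Huh7. Differences were also positive for the adhesion molecule ICAM1 at 1.97 ± 0.64, the protease inhibitor SERPINE1 at 2.72 ± 1.40 and the stress cytokine GDF15 at 1.93 ± 1.24. The stress ligand ULBP1, which natural killer cells recognise, had a difference of 1.6 ± 0.62. On the lower side stood PINK1-AS at −2.90 ± 0.35, whose reads cannot be parted from those of PINK1 where strand is unknown, SMLR1 at −2.02 ± 0.33 and the retrotransposon-derived gene PEG10 at −1.91 ± 1.21. CRBN had a difference of −0.25 ± 0.32, SERPINI1 of 0.28 ± 0.33 and CDKN1A of 0.93 ± 0.54.

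None passed: limma called 0 genes, with 265 at an unadjusted p under 0.05 where chance gives 793, and the lowest adjusted p was 0.557. The spread that all contrasts share may be too large for this one, so the absence of calls does not show equal responses. At least a 2-fold difference in both lines was seen for 86 genes higher and 64 lower. Opposite directions, in either order of the lines, were seen for 116. Across genes, the difference in PLC and that in Huh7 had a Pearson correlation of 0.017 and a Spearman correlation of 0.029. Within a line, the responses in control and senescent cells, which share no library, had a Pearson correlation of 0.545 in PLC and 0.694 in Huh7 and a Spearman correlation of 0.529 and 0.670. Of the genes changed at least 2-fold in both lines, 64 were higher in both states where 1.63 would be shared if the states were independent, and 106 were lower where 4.89 would be.

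As groups, 9 lists differed between the responses with the preset correlation, and 0 with an estimated one, and over all genes 0 of their members passed. The integrated stress response list was higher (camera adjusted p = 8.79e-10; adjusted p = 0.888 with an estimated correlation), 18 of 23 in both lines, with TRIB3 at 1.96 ± 0.70 and the cystine transporter SLC7A11 at 1.74 ± 0.52. NF-kB targets were higher (camera adjusted p = 1.4e-07; adjusted p = 0.888 with an estimated correlation), with medians of 0.96 in PLC and 0.06 in Huh7 and 11 of 19 members in opposite directions. The secretory factors, which share CCL20, were higher (camera adjusted p = 3.44e-05; adjusted p = 0.954 with an estimated correlation), 14 of 29 in both lines. Immediate early genes were higher (camera adjusted p = 5.15e-05; adjusted p = 0.954 with an estimated correlation), with medians of 1.27 in PLC and 0.43 in Huh7 and the phosphatase DUSP5 at 2.26 ± 0.60. Pro-apoptotic genes were higher in the difference (camera adjusted p = 0.00402, and 0.954 with an estimated correlation), with medians of 0.42 in PLC and −0.02 in Huh7. With ARV-825 their median hardly moved in senescent cells, at 0.009 in PLC and 0.014 in Huh7. In control cells it was −0.549 in PLC and −0.109 in Huh7. The difference thus came from a fall in PLC control cells. The BH3-only genes PMAIP1 and BBC3, which trigger mitochondrial cell death, were at 1.31 ± 0.52 and 1.20 ± 0.58. PMAIP1 rested on an estimated 2.2 to 51.8 fragments per library. Antigen presentation genes were higher (camera adjusted p = 0.00364; adjusted p = 0.954 with an estimated correlation), 10 of 12 in both lines, with HLA-C at 0.98 ± 0.45. The unfolded protein response was higher (camera adjusted p = 0.031; adjusted p = 0.954 with an estimated correlation), with medians of 0.01 in PLC and 0.42 in Huh7 and the sensor ERN1 at 1.07 ± 0.77. Cell cycle and E2F targets were lower (camera adjusted p = 0.000689; adjusted p = 0.954 with an estimated correlation), 44 of 59 in both lines, with the replication factor GINS2 at −1.01 ± 0.96. Markers of immune, endothelial and stromal cells were higher (camera adjusted p = 0.0123; adjusted p = 0.888 with an estimated correlation), but 4 were measured. Of these CD68, a lysosomal protein that is not restricted to macrophages, was at 1.68 ± 0.41 and was the 1 member past the threshold adjusted over the list alone. In the other lists of this paragraph 0 members passed adjusted over the list alone. Of the 9 calls, 7 were lost or turned without the PLC control vehicle library, 7 without Huh7 senescent ARV-825, 4 without PLC senescent vehicle, 2 without PLC control ARV-825, 2 without Huh7 control ARV-825, 1 without Huh7 control vehicle and 1 without Huh7 senescent vehicle. The mean cell cycle change relative to all genes turned positive without PLC control vehicle and without Huh7 senescent ARV-825. Over all libraries its median was −0.515 in PLC and −0.19 in Huh7. These turns therefore reflect how the fit fills in a missing library and show no reversal in either line. NF-kB targets and the integrated stress response were called with every library left out, both at the edge of the threshold without PLC control vehicle.

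**Figure D3:**
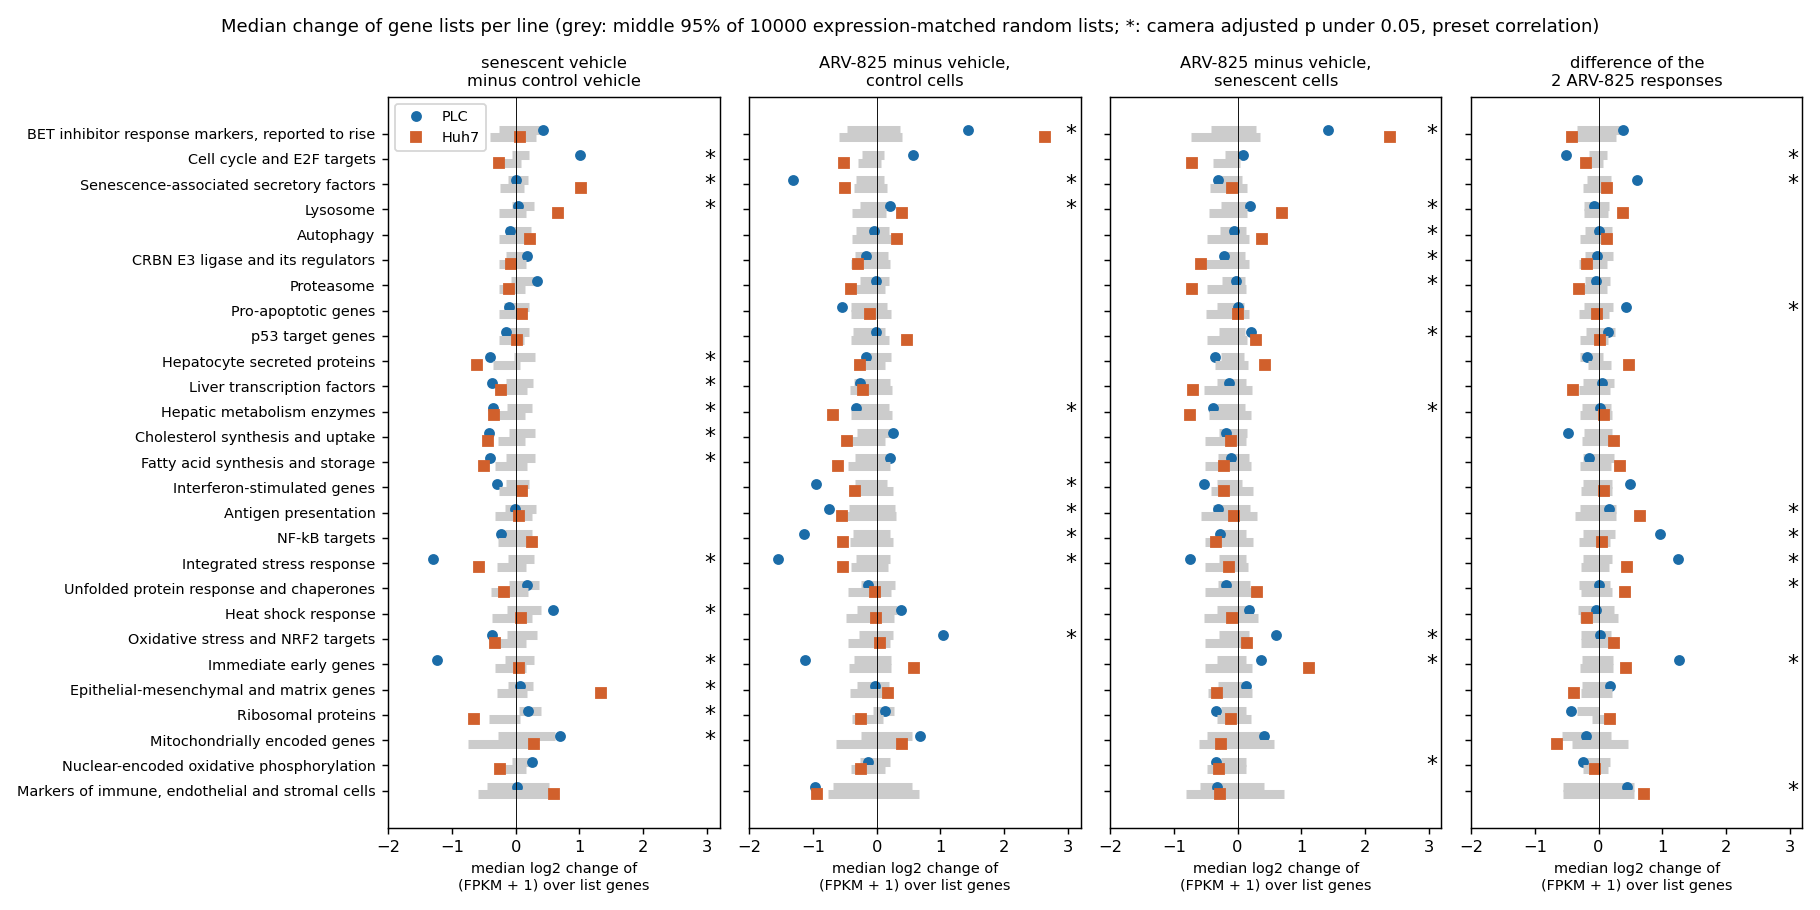
Median log2 change of FPKM + 1 of 27 gene lists in PLC (circles) and Huh7 (squares) for the 4 comparisons fixed before the data were examined, with grey bars for the middle 95% of 10000 random lists matched on expression and asterisks for camera calls with the preset correlation. The integrated stress response was at −1.29 in PLC and −0.58 in Huh7 in senescent against control cells and at −1.55 and −0.54 with ARV-825 in control cells.

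Averaged over both states, a comparison chosen after seeing the data, ARV-825 was compared with vehicle over 4 pairs of libraries from 2 lines. The fit took the 2 states of a line as independent, so the error of H2BC5 was 0.27 here against 0.38 in control cells alone. Responses correlated more between the states of a line (Pearson 0.545 in PLC and 0.694 in Huh7) than between the lines (0.406 in control and 0.380 in senescent cells). The errors of this average may therefore be too small and its calls too many, which was not tested. H2BC5 rose by 4.20 ± 0.27, H3C10 by 4.04 ± 0.27 and H2AC11 by 3.83 ± 0.30. SERPINI1 (chromosome 3, 167735243 to 167825568) rose by 1.49 ± 0.17 (limma adjusted p = 0.0142) and BRD2 (chromosome 6, 32968660 to 32981505), itself a target of the drug, by 0.96 ± 0.19 (limma adjusted p = 0.0395). The long noncoding RNA LINC01419 (chromosome 8, 83403758 to 83408900) rose by 3.08 ± 0.31. TM4SF4 fell by 3.44 ± 0.22, S100A16 by 3.03 ± 0.21, NAT8 by 2.88 ± 0.19 and SLC51B by 3.11 ± 0.28. The transcription factor ETV4, the ephrin EFNA2 and the noncoding RNA CCAT1 fell by 2.80 ± 0.31, 2.44 ± 0.28 and 2.62 ± 0.37.

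limma called 831 genes, 236 higher and 595 lower, with 4335 at an unadjusted p under 0.05. All 831 had the same direction in both lines, which the test itself brings about. Disagreement between the lines is part of its spread, so a gene with opposite directions could not pass. The share of calls that were higher was 28.4%, but 42.3% with TMM factors and 43.5% after quantile normalization, so the size of the excess of lower genes depended on the scaling. The excess was gone in some fits with few calls, with 22 higher and 7 lower without PLC control ARV-825 and 10 and 8 without Huh7 control ARV-825. MYC differed by −0.60 ± 0.46, HEXIM1 by 0.62 ± 0.28, CDKN1A by 0.88 ± 0.27, LMNB1 by −1.04 ± 0.42 and CRBN by 0.12 ± 0.16, and none of these passed. The count fell to 29 without PLC control ARV-825, 8 without PLC senescent vehicle, 18 without Huh7 control ARV-825, 10 without Huh7 senescent vehicle and 10 without Huh7 senescent ARV-825. It was 453 without PLC senescent ARV-825, 421 without Huh7 control vehicle and 0 without a filter or without the line block.

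As groups, 10 lists shifted in the averaged comparison with the preset correlation, and 0 with an estimated one. BET inhibitor response markers rose (camera adjusted p = 6.09e-10; adjusted p = 0.311 with an estimated correlation), with 6 of 9 passing over all genes and 8 adjusted over the list alone. Lysosome genes rose (camera adjusted p = 2.28e-05; adjusted p = 0.715 with an estimated correlation), with 3 of 31 passing over all genes and 3 adjusted over the list alone. NEU1 rose by 1.98 ± 0.27, MCOLN1 by 1.35 ± 0.27 and the proton pump subunit ATP6V0D1 by 1.11 ± 0.23. NRF2 targets rose (camera adjusted p = 0.00228; adjusted p = 0.715 with an estimated correlation), with 4 higher and 1 lower over all genes and 7 higher and 2 lower adjusted over the list alone. FTL rose by 2.23 ± 0.33, SRXN1 by 2.22 ± 0.33 and TXNRD1 by 1.56 ± 0.24. Integrated stress response genes fell (camera adjusted p = 0.000943; adjusted p = 0.715 with an estimated correlation), with 7 of 23 lower over all genes and 10 adjusted over the list alone. TRIB3 fell by 2.25 ± 0.35, STC2 by 1.96 ± 0.29 and the serine synthesis enzymes PHGDH and PSAT1 by 1.71 ± 0.21 and 1.5 ± 0.20. Interferon-stimulated genes fell (camera adjusted p = 0.0109; adjusted p = 0.715 with an estimated correlation), with medians of −0.91 in PLC and −0.12 in Huh7. Over all genes 3 were lower and 7 adjusted over the list alone, among them OAS3 and USP18, each at −1.38. NF-kB targets fell (camera adjusted p = 0.0109; adjusted p = 0.715 with an estimated correlation), with 1 lower over all genes and 8 adjusted over the list alone. Hepatic metabolism enzymes fell (camera adjusted p = 0.00749; adjusted p = 0.715 with an estimated correlation), with 2 lower over all genes and 6 adjusted over the list alone. ASS1 fell by 1.27 ± 0.25. The secretory factors (lower, camera adjusted p = 0.0478; adjusted p = 0.733 with an estimated correlation) had 1 member lower over all genes and 1 adjusted over the list alone. Proteasome genes (lower, camera adjusted p = 0.042; adjusted p = 0.906 with an estimated correlation) had medians of 0.03 in PLC and −0.54 in Huh7, with 1 member, PSMB6, lower over all genes and 0 adjusted over the list alone. Targets of p53 (higher, camera adjusted p = 0.0345; adjusted p = 0.715 with an estimated correlation) had 0 members past either threshold. Of the 10 calls, 4 were lost without PLC control vehicle, 3 without Huh7 control ARV-825, 3 without PLC senescent ARV-825, 2 without each of Huh7 control vehicle, Huh7 senescent ARV-825 and Huh7 senescent vehicle, and 1 without each of PLC control ARV-825 and PLC senescent vehicle. The 4 calls lost without PLC control vehicle were the integrated stress response (camera adjusted p = 0.0934), NF-kB targets (0.101), interferon-stimulated genes (0.154) and the secretory factors (0.323).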

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

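The tests on single libraries, on the spread of values, on cell cycle genes and on other splits of the libraries were chosen only after the result was seen, as was the averaged comparison. The tests on gene length, on RNA without a poly(A) tail and on NF-kB targets had predictions written before.

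By the list median, in each line, integrated stress response genes were below control vehicle in senescent cells and with ARV-825 in control cells. The camera adjusted p with an estimated correlation was 0.701 and 0.678. In both lines 13 of 23 members were lower in senescent cells, with 10 in opposite directions. With ARV-825 in control cells 16 of 23 were lower in both lines and 0 higher. Their difference between the ARV-825 responses had a camera adjusted p of 8.79e-10 (0.888 with an estimated correlation). The PLC control vehicle library alone is argued against, since in Huh7 the list median stood at percentile 0.0 of 10000 random lists in senescent against control cells and at percentile 0.19 with ARV-825 in control cells; without that library the camera adjusted p was 0.0376 and 0.0335, though the call in the averaged comparison was lost (0.0934). A different spread of values between libraries is also argued against, with a camera adjusted p of 2.93e-11 after quantile normalization. What stays open is that the Huh7 and PLC control vehicle cultures may both have differed from the rest, for example in nutrients or density, which was not tested. An effect of the state and of the drug, which the design names, stays open as well and untested.

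Histone genes were higher with ARV-825: of 58 replication-dependent genes past the filter, 55 were higher in both lines in the averaged comparison, with median log2 changes of 1.36 in PLC and 2.98 in Huh7. A gene could pass the filter only through its ARV-825 libraries, so the count may be too high. H2AC11 was such a gene, at 0.618 and 0.902 FPKM with vehicle in PLC and 1.075 and 0.958 in Huh7. Short genes raised as a class are argued against, as both lines stood at percentile 100 of random lists matched on length and expression. More cells copying DNA is argued against in Huh7, where cell cycle genes stood at percentile 0.0, but stays open for part of the rise in PLC, where they stood at percentile 100; in senescent PLC cells their median was 0.08 against 1.5 for histone genes, and in senescent against control PLC cells 1.01 against 0.30. More RNA without a poly(A) tail in the ARV-825 libraries may also account for part of it, as 15 such RNA genes stood at percentile 99.82 or above in both lines, though with medians of only 0.37 in PLC and 0.59 in Huh7. Histone RNA that gained a tail and an effect of BET degradation were not tested and stay open beside these.

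NF-kB targets were called lower with ARV-825 in control cells (camera adjusted p = 3.95e-05; adjusted p = 0.678 with an estimated correlation) and were called different in the response of senescent cells (camera adjusted p = 1.4e-07; adjusted p = 0.888 with an estimated correlation). The PLC control vehicle library alone cannot be told apart from an effect of the state: in Huh7 the list median of the difference stood at percentile 84.52, neither at the edge of the random lists nor in their middle. Without that library the list was still called, but at the edge of the threshold (camera adjusted p = 0.047), and its mean change relative to all genes went from 0.80 to 0.39. Secretory factors, which share CCL20 and CXCL8, had a camera adjusted p of 3.44e-05 for the same difference (adjusted p = 0.954 with an estimated correlation), and 0.79 without PLC control vehicle, 0.148 without Huh7 senescent ARV-825 and 0.383 without PLC senescent vehicle. A state effect, which the design names, may be part of it and was not tested apart from the library.

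For ARV-825 against vehicle over all 8 libraries with the cell line as a block, 1324 genes passed in the real split. This fit had no term for the state, unlike the averaged comparison with 831 calls. The 18 splits with 2 libraries of each line on each side are too few for a share under 0.05, and 1 of them, the real one, gave as many genes, with 1 as the highest other count. The other 16 splits part the lines unevenly, so that they overlap with the block, and gave 0 genes. In these and in the other balanced splits the drug effect counts as spread. That keeps their counts low whatever the cause, so they cannot decide the question. The split by line could not be fitted with the block, and without it gave 4561 genes, which points to the lines as the main structure of the samples.

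Other lists differed between the responses of senescent and control cells by camera with the preset correlation. The camera adjusted p was 0.000689 for cell cycle and E2F targets, 0.00402 for pro-apoptotic genes and 0.00364 for antigen presentation genes (adjusted p = 0.954 for each with an estimated correlation). The camera adjusted p was 0.031 for the unfolded protein response, 5.15e-05 for immediate early genes and 0.0123 for markers of immune, endothelial and stromal cells (adjusted p = 0.954, 0.954 and 0.888 with an estimated correlation). Over all libraries the cell cycle medians of the difference were −0.515 in PLC and −0.19 in Huh7, and the immediate early medians 1.266 and 0.427. A fit with a library left out fills it in from the difference between the lines in the other groups. A list can thus turn though neither line reversed. Without PLC control vehicle, the mean change relative to all genes turned positive for the cell cycle list and negative for the immediate early list. The calls of the pro-apoptotic, antigen presentation, unfolded protein and marker lists were lost without it (camera adjusted p = 0.427, 0.194, 0.14 and 0.135). Without Huh7 senescent ARV-825, the mean cell cycle change turned positive in the same way and the other calls of this paragraph were lost. Without PLC senescent vehicle, the cell cycle, pro-apoptotic and marker calls were lost (camera adjusted p = 0.0827, 0.131 and 0.0821). Without PLC control ARV-825, the pro-apoptotic and unfolded protein calls were lost (camera adjusted p = 0.0813 and 0.289). Without Huh7 control ARV-825, the antigen presentation and marker calls were lost (camera adjusted p = 0.0665 and 0.109). The unfolded protein call was also lost without Huh7 control vehicle and without Huh7 senescent vehicle (camera adjusted p = 0.0731 and 0.804).

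Further results had opposite directions in the lines, and the difference between lines was not tested for any of them. Cell cycle genes had median log2 changes of 1.014 in PLC and −0.268 in Huh7 in senescent against control cells, 0.566 and −0.509 with ARV-825 in control cells, and 0.082 and −0.711 with ARV-825 in senescent cells. The PLC values of senescent against control cells and of ARV-825 in control cells share the PLC control vehicle library, so they are not independent. MKI67 was at 7.474 FPKM there. It was at 17.379 in PLC control ARV-825, 15.669 in PLC senescent vehicle and 19.998 in PLC senescent ARV-825. Without PLC control vehicle, the mean cell cycle change relative to all genes changed direction in both comparisons. The mean of immediate early genes did so too. Nuclear envelope and chromatin genes lost in senescence were at 0.654 in PLC and −0.411 in Huh7 in senescent against control cells. Hepatocyte secreted proteins were at −0.35 in PLC and 0.436 in Huh7 with ARV-825 in senescent cells. Cholesterol genes were at 0.252 in PLC and −0.469 in Huh7 with ARV-825 in control cells, and immediate early genes at −1.121 and 0.582. NF-kB targets were at −0.23 in PLC and 0.256 in Huh7 in senescent against control cells. MYC was at 0.63 in PLC and −0.59 in Huh7 in senescent against control cells and at −1.5 and 0.51 with ARV-825 in control cells. MKI67 was at 0.98 in PLC and −0.54 in Huh7 in senescent against control cells, and ALB at −1.33 and 0.64 with ARV-825 in senescent cells.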

How the results depend on the processing

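The averaged comparison, the block by pair of libraries and the library doubted were chosen after the result was seen; the other settings were chosen before the data were examined. Where a count or list moved, the cause was not tested, except that a fit without the line block or on fewer libraries has fewer degrees of freedom or more spread, and that rescaling to TPM acts like a smaller pseudocount.

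With ARV-825 in control cells, 14 genes were called as reported, 23 with a pseudocount of 0.1, 0 with 5, 0 without a filter, 42 with a filter at 5 FPKM, 90 rescaled to TPM, 0 without the line block, 2 from its 4 libraries alone, 7 without the trend and 53 among protein-coding genes; leaving out each library gave 0 to 16. With ARV-825 in senescent cells, 0 were called as reported by limma with 2263 at an unadjusted p under 0.05, 3 with a pseudocount of 0.1, 9 with a filter at 5 FPKM, 5 rescaled to TPM, 14 from its 4 libraries alone and 9 among protein-coding genes. Senescent against control cells and the difference of responses had 0 calls by limma as reported, with 788 and 265 at an unadjusted p under 0.05, and 0 to 1 on leaving out each library, 1 being without Huh7 control vehicle. The averaged comparison had 831 as reported, 190 with a pseudocount of 5, 0 without a filter, 1282 rescaled to TPM, 0 without the line block and 1741 with a block by pair of libraries, of which 807 were shared. Leaving out each library gave 8 (PLC senescent vehicle) to 679 (PLC control vehicle), of which 8 and 454 were shared.

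Counts of genes changed at least 2-fold in both lines moved with the pseudocount, as low genes weigh more with a small one. In the order pseudocount 0.1, pseudocount 5, rescaled to TPM, at least 1.5-fold and at least 3-fold, senescent against control cells gave 220, 14, 173, 275 and 15 higher (69 as reported) and 204, 19, 169, 287 and 9 lower (55). ARV-825 in control cells gave 547, 43, 417, 681 and 41 higher (177) and 900, 78, 850, 1205 and 64 lower (333). ARV-825 in senescent cells gave 393, 41, 327, 482 and 49 higher (146) and 735, 27, 657, 1018 and 33 lower (233). The difference of responses gave 294, 15, 243, 338 and 14 higher (86) and 271, 5, 204, 304 and 10 lower (64), and 43 and 24 with a filter at 5 FPKM. Genes changed in opposite directions, in the same order, numbered 274, 17, 211, 352 and 12 for senescent against control cells, and 521, 19, 413, 583 and 22 for the difference (58 with the filter at 5 FPKM). They numbered 218, 8, 172, 243 and 11 with ARV-825 in control cells (39 as reported), and 282, 8, 217, 254 and 8 in senescent cells (39). The opposite count pools 2 patterns, so it is set against the higher and lower counts together. Those exceeded it in these settings for senescent against control cells and, by a small margin, for the difference.

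The correlation across genes of the PLC and Huh7 responses to ARV-825 was 0.406 in control cells as reported, 0.386 with a pseudocount of 0.1, 0.380 with 5, 0.360 without a filter and 0.443 with a filter at 5 FPKM. In senescent cells it was 0.380, and 0.331, 0.405, 0.330 and 0.465 with the same settings and 0.348 rescaled to TPM.

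With an estimated correlation, 0 lists were called in any comparison. Senescent against control cells had 14 lists as reported and 8 to 18 on leaving out each library. ARV-825 in control cells had 9, 18 without a filter and 9 to 17 on leaving out each library. ARV-825 in senescent cells had 10, 6 with a pseudocount of 0.1 and 16 without a filter. The difference had 9, and 4 to 19 on leaving out each library, and the averaged comparison 10, and 18 without a filter. Of the 52 list calls, 38 held with a pseudocount of 0.1, without a filter and after quantile normalization, and 12 with every library left out. Those lost under these settings were secretory factors, hepatic metabolism and mitochondrial genes in senescent against control cells. With ARV-825 in senescent cells they were autophagy, E3 ligase, proteasome, immediate early and oxidative phosphorylation genes. In the difference they were antigen presentation, unfolded protein and marker lists, and in the average secretory factors, proteasome and p53 targets.

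Leaving out a library turned 24 list results, which means a changed direction and a call in at least 1 of the 2 fits. A further 177 list values changed direction with a library left out and no call in either fit. As such a fit fills in the missing library from the other groups, a turn need not mean that a line reversed. Values are the mean log2 change less that of all genes, as reported and then from lowest to highest. In senescent against control cells they were 0.36 for cell cycle, −0.36 to 1.07; 0.40 for secretory factors, −0.23 to 1.04; 0.05 for nuclear envelope, −0.54 to 0.65; 0.08 for homologous recombination, −0.35 to 0.52. Interferon-stimulated genes were at −0.10, from −0.45 to 0.25, NF-kB targets at −0.01, from −0.42 to 0.40, immediate early genes at −0.53, from −1.40 to 0.35, and ribosomal genes at −0.24, from −0.52 to 0.044. With ARV-825 in control cells, cell cycle went from −0.62 to 0.81, nuclear envelope from −0.60 to 0.59, cholesterol from −0.41 to 0.37, immediate early genes from −1.11 to 0.63 and ribosomal genes from −0.27 to 0.29. With ARV-825 in senescent cells, cell cycle went from −0.92 to 0.34, proteasome from −0.67 to 0.066, homologous recombination from −0.49 to 0.31 and hepatocyte secreted proteins from −0.53 to 0.50. In the difference, cell cycle went from −1.10 to 0.33, lysosome from −0.29 to 0.62, proteasome from −0.50 to 0.23, cholesterol from −0.46 to 0.31, immediate early genes from −0.052 to 1.69 and matrix genes from −0.55 to 0.62. In the averaged comparison, cell cycle went from −0.46 to 0.26.

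For named genes, 2779 values kept direction and side of the threshold, 272 no longer passed and 41 newly passed. A further 77 changed direction with no call in either fit, and 0 changed direction with a call in at least 1 fit. For gene lists, the numbers were 2001, 151, 141, 200 and 27. Depth limits low genes: 1 FPKM in a gene of 2 kb stood for 12 to 13.2 fragments, so that changes in genes near the filter rest on few fragments. With 2 lines, the line block pairs libraries across groups, and without that pairing 0 genes were called with ARV-825 in control cells.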

Other observations

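The reading of cell cycle genes beside histone genes, and the counts per list in this part, were chosen only after the result was seen. Histone genes and cell cycle genes moved apart in Huh7 with ARV-825: in control cells the 58 histone genes past the filter had a median log2 change of 3.32, while cell cycle and E2F targets were at −0.51 and LMNB1 at −1.80. In PLC the histone median was 1.39 and the cell cycle median 0.57, and MKI67 was higher by 1.12. Of the histone genes, 35 were at least 2-fold higher in both lines in control cells and 37 in senescent cells. In senescent against control cells with vehicle their median was 0.30 in PLC and −0.03 in Huh7.

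Some lists fixed before the data were examined, on processes linked to senescence or to BET proteins, showed no camera call in the comparisons below. CDK inhibitors had a camera adjusted p of 0.745 and p53 targets of 0.437 in senescent against control cells. MYC targets had a camera adjusted p of 0.253 with ARV-825 in control cells and 0.313 in senescent cells, and the BET family of 0.363 and 0.0885. A missed threshold does not show that these genes did not differ.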
